A study of Pseudomonas putida with 21 samples.

How the data were processed

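The series measured RNA of Pseudomonas putida KT2440, a soil bacterium, on 21 one-colour Agilent arrays, with 1 sample labelled with Cy3 per array. Per the labels, 4 control arrays came from surface colonies kept at -0.5 kPa, and 11 arrays came from surface colonies kept at a matric potential of -0.4 MPa for 4 h (4 arrays), 24 h (3 arrays) or 72 h (4 arrays). Surface colonies exposed to polyethylene glycol 8000 (PEG), a solute too large to enter the cell, gave 2 arrays at -0.5 MPa and 1 array at -1.0 MPa. Liquid cultures gave 2 arrays under a gas pressure of 0.4 MPa and 1 array at 0.1 MPa. The length of the PEG and gas treatments was not given in the sources used here. For replicate 1 of the 72 h group the title gave 72 h and the time field gave 24 h, and it was kept in the 72 h group. The labels did not say whether replicates were separate cultures, so the p-values measure only the spread between these samples.

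Each array had its own deposited scanner file, and the values were intensity values that Agilent Feature Extraction 10.5.1.1 had corrected for background and spatial trend without scaling between arrays, per the file headers. The deposited series table held log2 values, which per the submitters' processing notes were made with limma (version not given). The columns of that table matched log2 values of the median spot signal after quantile normalization in 2 separate sets of columns. Its columns for control replicates 3 and 4 matched the scanner files of control replicates 1 and 2, so the table held no values from the scanner files of control replicates 3 and 4. The intensity values were therefore used throughout, and the table served only as an alternative.

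Each array carried 15744 spots, of which 536 control spots were left out. The 15208 gene spots held 10689 probes, of which 6170 were spotted once and 4519 were spotted in duplicate. The processed signal of each spot was divided by the 75th percentile of the gene spots of its array, floored at 0.001 and taken to log2. No scaled value lay at the floor and 0 gene spots were saturated. Spots were averaged per probe and probes per gene, which gave 5349 genes, 5340 of them with 2 probes and 9 with 1 probe. Genes were kept when a probe was well above background on at least 3 arrays, which removed none. A value was missing on at least 1 array for 49 genes, and 5300 genes had a value on all 21 arrays.

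Group means of all 21 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 groups, 13 residual degrees of freedom, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Groups with 1 array took the spread of the other groups. Each matric group was compared with the controls and with the other matric groups, both PEG groups with the controls and with each other, the PEG group at -0.5 MPa with the mean of the 3 matric groups, and the gas pressure group with the liquid culture at 0.1 MPa. The groups, the tests, the rule for naming genes and most alternatives were chosen before the data were examined.

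Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted within each family of lists, and again with the correlation between genes estimated from the data. Beside these, fry tested whether the genes of a list moved, on balance, in one direction, without comparing the list with other genes. Of 33 lists fixed before the data were examined, 10 were given by locus tag, 1 of them only in part, and could be used. The list for N-acetylglutaminylglutamine amide (NAGGN) was the 3 locus tags of a fixed list for osmoprotection. The betaine and other genes of that fixed list were given by symbol and dropped out. Betaine genes were tested in a list added later. The other lists were given by gene symbol, and the array annotation gave no symbols. The reference table covered another strain, and 0 of its tags matched. A further 14 lists were written by locus tag from general knowledge of the strain after the array annotation had been read and before any fold change had been computed.

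The rule for naming genes took, for each list and matric comparison, up to 3 called members with the largest change, or up to 2 with the smallest p where none was called. Without regard to lists it took the largest 2 in each direction among called genes in which every array of one group lay beyond every array of the other. Genes named in one comparison were followed in others. Only locus tags are given, since no symbol table for this strain was at hand.

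The scanner headers placed the arrays on 3 slides. Slide 1 held the 4 h arrays, 72 h replicates 1 and 2 and control replicate 1. Slide 2 held the 24 h arrays, 72 h replicates 3 and 4 and control replicate 2. Slide 3 held the PEG and liquid culture arrays and control replicates 3 and 4. Time and slide were therefore partly confounded, and fits with slide as a block and fits within 1 slide are given beside the results. The samples were treated as unpaired. Deviations of arrays from their group means were correlated between arrays of the same replicate number. Over 21 pairs of arrays the correlation ranged from -0.849 to 0.860, and 9 of the 21 exceeded 0.1. Arrays with a narrow signal range share deviations, so this check cannot decide whether the samples were paired.

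The alternatives chosen before the data were examined were quantile normalization, a floor of 0.01, the median of the probes, no filter, a stricter filter (5338 genes), a minimum of 2-fold, an intensity trend with robust spread, array weights, a fit of only the groups compared, the replicate number or the slide as a block, 72 h replicate 1 counted as 24 h, split controls for comparisons that share them, and omission of each replicate. Added after the data were seen were fits without control replicates 3 and 4 (19 arrays), without control replicate 3 and the 6 arrays with a narrow signal range (14 arrays), within 1 slide, from the values of the series table, and with normexp correction (offset 50) of the median signal. The same procedure was tested on simulated data with known changes for the 4 h comparison. It recovered 9% of genes with a log2 change of 1 and 52% of genes with a log2 change of 2, against 5% and 58% without control replicates 3 and 4. The number of arrays limited the precision.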

Results

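RNA levels of 5349 genes of Pseudomonas putida KT2440 were measured on 21 arrays in 8 groups. Surface colonies gave 4 control arrays, 4 arrays after 4 h, 3 after 24 h and 4 after 72 h of matric stress at -0.4 MPa, and 2 arrays with PEG at -0.5 MPa and 1 at -1.0 MPa. Matric stress is the loss of free water that bacteria meet in drying soil, and PEG lowers the water potential with a dissolved polymer instead. Liquid cultures gave 2 arrays under a gas pressure of 0.4 MPa and 1 at 0.1 MPa. Values are log2 of the signal relative to the 75th percentile of each array.

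The 75th percentile of the gene spots ranged from 746 to 4742 intensity units, and 98.4 to 100% of the gene spots of each array were well above background. The range of signal differed between arrays of the same group. The 75th percentile was 4.08 to 8.77 times the 1st percentile on 6 arrays and 20.1 to 81.1 times the 1st percentile on the other 15 (control replicate 4, 4 h replicates 3 and 4, 24 h replicate 1 and 72 h replicates 2 and 3 were the 6 narrow arrays). Control replicates 1 and 2 correlated with each other across genes at 0.964. The scanner file of control replicate 3 correlated with the liquid culture arrays at 0.986 to 0.994, against 0.759 with control replicate 1 and 0.781 with control replicate 2. The scanner file of control replicate 4 correlated with control replicates 1 and 2 at 0.562 and 0.487. Because the deposited series table held no values from the files of control replicates 3 and 4, the number of called genes in each comparison is also given without them. That fit kept narrow arrays in the matric groups and left only wide ones among the controls. Its median log2 fold change of all genes was 0.20, 0.28 and 0.44 at 4, 24 and 72 h. Without control replicate 3 and the narrow arrays these medians were -0.30, -0.010 and -0.19.

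**Figure D1:**
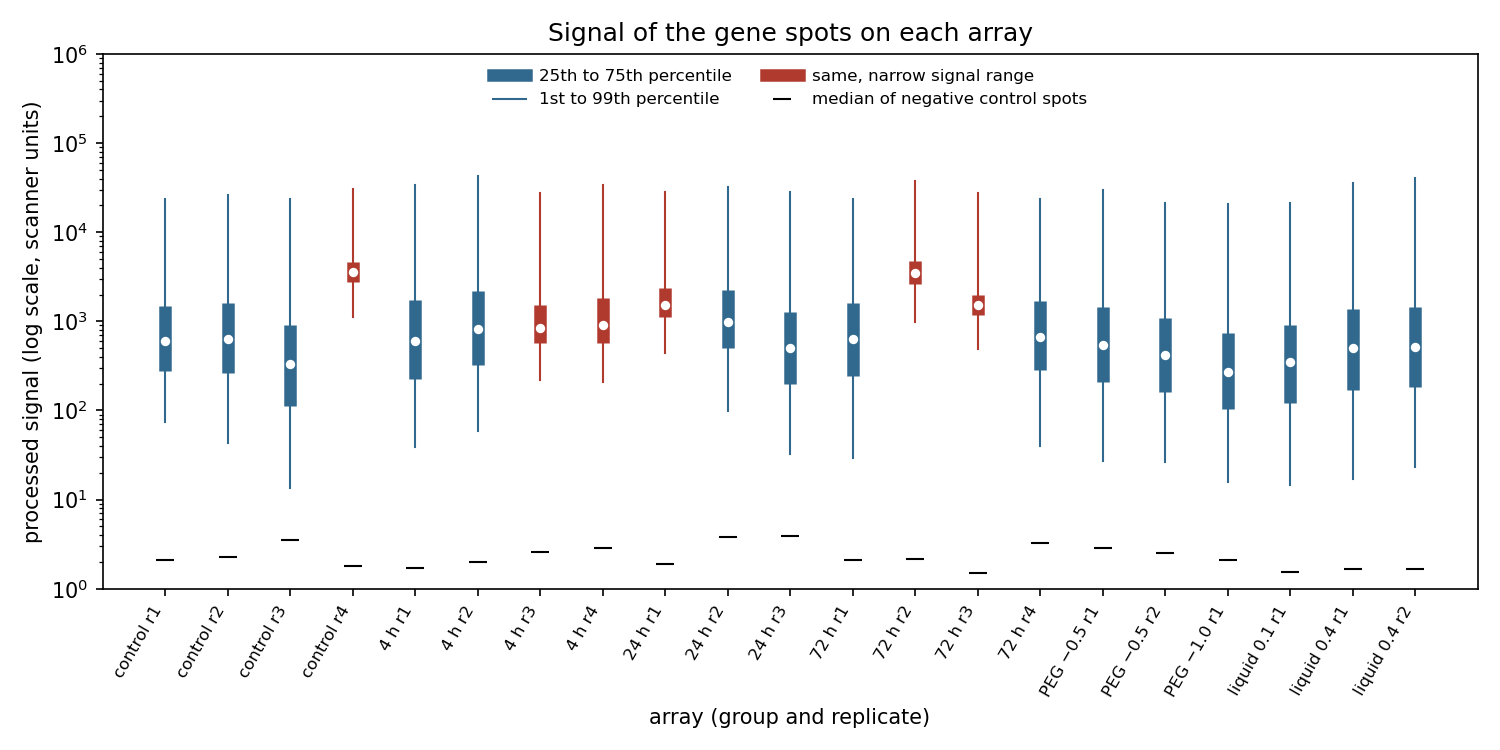
Processed signal of the gene spots on each of the 21 arrays, on a log axis in scanner units, with thick bars from the 25th to the 75th percentile, thin lines from the 1st to the 99th, white dots at the median, and dashes at the median of the negative control spots. On the 6 narrow arrays, drawn in red, the 1st percentile lay at 210 to 1115, against 13.6 to 99.3 on the others, while the negative control spots lay at 1.51 to 3.89 on all arrays.

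After 4 h of matric stress the genes for alginate, an exopolysaccharide that holds water around cells, stood higher than in the controls. The median log2 fold change of the 12 alginate genes was 1.90, and all 12 lay above 0. PP_1288 rose 7.12-fold (log2 2.83, SE 0.67, adjusted p = 0.0111), from -3.63 ± 2.00 (SD, n = 4) in the controls to -0.80 ± 0.22 (SD, n = 4), and the log2 change was 2.14 without control replicate 3 and 3.71 without control replicate 4. PP_1278 rose 5.90-fold (log2 2.56, SE 0.40, adjusted p = 0.000505), and PP_1280 rose 6.23-fold with adjusted p = 0.0367, a call that stayed without control replicate 4 and was lost without any one of the other 7 arrays (adjusted p = 0.0687 to 0.120). Its log2 change of 2.64 was 1.94 without control replicate 3 and 3.53 without control replicate 4. Of the 12 genes 6 were called over all genes and 11 were called when adjusted over the list alone. The alginate list passed camera with adjusted p = 2.52e-08, against adjusted p = 0.170 with an estimated correlation. The median was 2.22 and 11 genes were called without control replicates 3 and 4.

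The pea cluster, which encodes another exopolysaccharide of the biofilm matrix, moved the opposite way at 4 h. All 11 pea genes lay below 0 with a median of -0.94, 7 were called lower, and 9 were called when adjusted over the list alone. PP_3135 fell by 1.84 on the log2 scale (SE 0.28, adjusted p = 0.000433), from 0.92 ± 0.68 (SD, n = 4) to -0.92 ± 0.21 (SD, n = 4). PP_3134 changed by -2.03 (adjusted p = 0.00124) and PP_3138 by -1.53 (adjusted p = 0.00484). The pea list passed camera with adjusted p = 3.76e-09, against adjusted p = 0.0791 with an estimated correlation. When control replicates 3 and 4 were left out the median of the list was 2.82-fold lower than in the controls, 9 genes were called, and the list also passed with an estimated correlation (adjusted p = 0.0338). Its shift relative to all genes went from -0.87 to -1.42 without control replicate 4.

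Compatible solutes, among them NAGGN, trehalose and betaine, are small molecules that cells collect to hold water. The NAGGN locus and the cluster for trehalose and glycogen rose at 4 h, while the betaine locus was not called (median -0.13, adjusted p = 0.762). All 3 genes of the locus for N-acetylglutaminylglutamine amide (NAGGN) were called, with a median of 3.29. PP_1750 rose 10.3-fold (log2 3.36, SE 0.37, adjusted p = 3.26e-05), from 0.67 ± 0.21 (SD, n = 4) to 4.02 ± 0.42 (SD, n = 4), PP_1748 rose 9.79-fold (log2 3.29, 2.56 without control replicate 3) and PP_1749 rose 5.40-fold. The NAGGN list passed camera with adjusted p = 2.79e-06 and with an estimated correlation (adjusted p = 0.0186). In the cluster for trehalose and glycogen 8 of 11 genes rose, 10 when adjusted over the list alone, with a median of 1.84. PP_4060 rose 7.74-fold (log2 2.95, SE 0.50, adjusted p = 0.000832, log2 2.33 without control replicate 3), PP_4050 rose by 2.91 and PP_4051 by 2.65 on the log2 scale. The trehalose and glycogen list passed camera with adjusted p = 5.97e-10, against adjusted p = 0.0580 with an estimated correlation. The medians were 3.04 and 1.33 without control replicates 3 and 4, and both lists then passed with an estimated correlation at adjusted p = 0.0338.

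The envelope stress locus algU-muc, which controls alginate genes in pseudomonads, rose at 4 h with a median of 2.59. PP_1428 rose 6.34-fold (log2 2.66, SE 0.44, adjusted p = 0.000714), and PP_1427 and PP_1429 rose 6.57-fold and 5.75-fold (log2 2.72 and 2.52, against 1.97 and 1.87 without control replicate 4). The list passed camera with adjusted p = 0.0013, against adjusted p = 0.0612 with an estimated correlation. Its median was 2.00 without control replicates 3 and 4, and its shift relative to all genes went from 2.66 to 1.68 without control replicate 4. Genes for uptake and breakdown of aromatic acids included PP_1378, which rose 14.7-fold (log2 3.87, SE 0.45, adjusted p = 4.36e-05), PP_1380 (3.71-fold) and PP_1379 (3.18-fold). The median of the 17 genes of that list was 1.42 (camera adjusted p = 2.68e-05, adjusted p = 0.393 with an estimated correlation) and -0.16 without control replicates 3 and 4, so the direction of the list rested on those arrays. Its shift of 1.48 relative to all genes was 0.76 without control replicate 3 and 2.08 without control replicate 2, and its call was lost without control replicate 3 and the narrow arrays (adjusted p = 0.398), while PP_1378 kept a change of 3.40.

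In the cluster for the flagellum and chemotaxis, the machinery of swimming, 6 of 59 genes were called higher and 1 lower at 4 h, against 12 and 1 adjusted over the list alone. PP_4395 rose 6.07-fold (log2 2.60, adjusted p = 0.00413), PP_4396 rose 4.92-fold, and PP_4364 changed by -2.09 (adjusted p = 0.000812). The flagellum list had a median of 0.39 and passed camera with adjusted p = 0.0103, against adjusted p = 0.599 with an estimated correlation. Its call was lost without 4 h replicate 1 (adjusted p = 0.158) or control replicate 4 (adjusted p = 0.309), where its shift relative to all genes went from 0.45 to 0.076 and 0.14, and the shift was 0.83 without 4 h replicate 3 and 0.76 without control replicate 3.

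Lists for respiration, cell division, adhesion and storage stood lower at 4 h. The cluster for peptidoglycan and cell division had a median of -0.69 with 3 of 14 genes called (camera adjusted p = 2.68e-05, adjusted p = 0.342 with an estimated correlation), among them PP_1333 (-1.15) and PP_1334 (-1.05). Those calls were lost without 4 h replicate 1 (adjusted p = 0.0754 and 0.0906), 4 h replicate 2 (0.0684 and 0.0588) or control replicate 2 (0.0520 and 0.0615), and that of PP_1334 also without 4 h replicate 4 (0.0518). The shift of that list relative to all genes went from -0.63 to -0.24 without control replicate 3, and its call was lost without control replicate 3 and the narrow arrays (adjusted p = 0.190) and within slide 1 (0.228). NADH dehydrogenase genes had a median of -0.71 (adjusted p = 0.000148, adjusted p = 0.342 with an estimated correlation), with PP_4126 called at -1.25 (adjusted p = 0.0562 without 4 h replicate 1). Their shift of -0.65 was -0.30 without control replicate 3 and -1.04 without control replicate 4, and the call was lost without control replicate 3 and the narrow arrays (adjusted p = 0.206) and within slide 1 (0.0846). The terminal oxidases had a median of -0.68 (adjusted p = 0.0449, adjusted p = 0.464 with an estimated correlation), with PP_4258 called at -1.41. The list lost its call with quantile normalization (adjusted p = 0.0888), without control replicates 3 and 4 (0.318), and without 4 h replicates 3 (0.243) or 4 (0.0915). Its shift went from -0.62 to 0.28 without control replicate 3, -0.34 without 4 h replicate 3, -0.38 without control replicate 2 and -1.01 without control replicate 4. The direction also turned with slide as a block (0.054), within slide 1 (0.047) and without control replicate 3 and the narrow arrays (0.34).

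The lap locus for a surface adhesin had a median of -0.61 (adjusted p = 0.0449, adjusted p = 0.217 with an estimated correlation), with PP_0168 called at -1.47, and lost its call with slide as a block (adjusted p = 0.0942), with quantile normalization (0.292), without control replicates 3 and 4 (0.0629), and without 4 h replicate 3 (0.0649) or 4 (0.0768) or control replicate 1 (0.0519) or 3 (0.110). It was also lost within slide 1 (0.0846) and, at a shift of -0.43, without control replicate 3 and the narrow arrays, and the shift of -0.55 was -0.32 without control replicate 3 and -1.03 without control replicate 4. The polyhydroxyalkanoate cluster, which stores carbon, had a median of -0.77 (adjusted p = 0.0136, adjusted p = 0.0791 with an estimated correlation), with 0 of 6 genes called by limma over all genes and 1 adjusted over the list alone, and the list call was lost without control replicate 3 (adjusted p = 0.0777). Prophage loci had a median of -0.22 (adjusted p = 0.0152, adjusted p = 0.752 with an estimated correlation), with PP_2292 called at -2.23 and PP_3852 at 1.92, and the call was lost with slide as a block (adjusted p = 0.0506) and without 4 h replicate 1 (adjusted p = 0.131) or 2 (0.0654) or control replicate 2 (0.0722) or 4 (0.385). The shift of the prophage list, -0.16, was -0.053 without 4 h replicate 1, -0.28 without 4 h replicate 3, -0.24 without 4 h replicate 4, -0.076 without control replicate 2, -0.35 without control replicate 3 and -0.026 without control replicate 4. The type VI secretion loci had a median of -0.21 (adjusted p = 0.0405, adjusted p = 0.752 with an estimated correlation), with PP_3108 called at -1.09. That list lost its call within slide 1 (adjusted p = 0.629) and without 4 h replicate 1 (0.131) or 2 (0.103) or control replicate 3 (0.0777), and its shift of -0.15 was -0.028, -0.061, -0.30 and -0.25 without 4 h replicates 1, 2, 3 and 4, and -0.34, -0.23 and 0.095 without control replicates 2, 3 and 4. The type VI secretion list reversed to a shift of 0.13 with slide as a block (camera adjusted p = 0.804). It was 0.075 without control replicates 3 and 4 (0.661), and its call was also lost without control replicate 4 (0.365). PP_3108 lost its call without 4 h replicate 1, 3 or 4 or control replicate 2 or 3 (adjusted p = 0.0506 to 0.123). The cellulose cluster (median -0.23, adjusted p = 0.348) and the peb exopolysaccharide cluster (median -0.84, adjusted p = 0.0640) were not called.

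At 4 h limma called 475 genes, 363 higher and 112 lower, against 974 genes at an unadjusted p under 0.05. In 348 of the risen and 97 of the fallen genes every stress array lay beyond every control array. A call on the same arrays makes this likely, so it adds no support. Outside the lists, PP_3265 rose 30.9-fold (log2 4.95, SE 0.83, adjusted p = 0.000827, log2 3.68 without control replicate 3) and PP_1502 rose 26.3-fold (log2 4.71, SE 0.52, adjusted p = 3.26e-05). PP_2006 changed by -3.09 (SE 0.66, adjusted p = 0.00576) and PP_1002 by -3.02 (SE 0.59, adjusted p = 0.00289, and -3.62 without control replicate 4) on the log2 scale. The count was 789 without control replicates 3 and 4, 472 higher and 317 lower, of which 424 were also among the 475. The median of all genes moved from -0.06 to 0.20 with that omission. The balance of directions depended on the arrays and values used, since 642 genes were higher and 763 lower without control replicate 3 and the narrow arrays, and 418 higher and 412 lower in the series table. A fit of only the groups compared gave 242 genes, 223 higher and 19 lower. With slide as a block 228 genes were higher and 141 lower, and within slide 1, with 4 stress arrays and 1 control array, 56 were higher and 24 lower. Of the 10 fixed lists 8 passed camera, 1 with an estimated correlation and 5 with fry, and 5 passed camera without 4 h replicate 1 or without control replicate 4. Within slide 1 the shift of a list relative to all genes was 1.71 for alginate, -1.52 for pea, 1.29 for trehalose and glycogen, 2.65 for NAGGN and 1.85 for algU-muc.

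**Figure D2:**
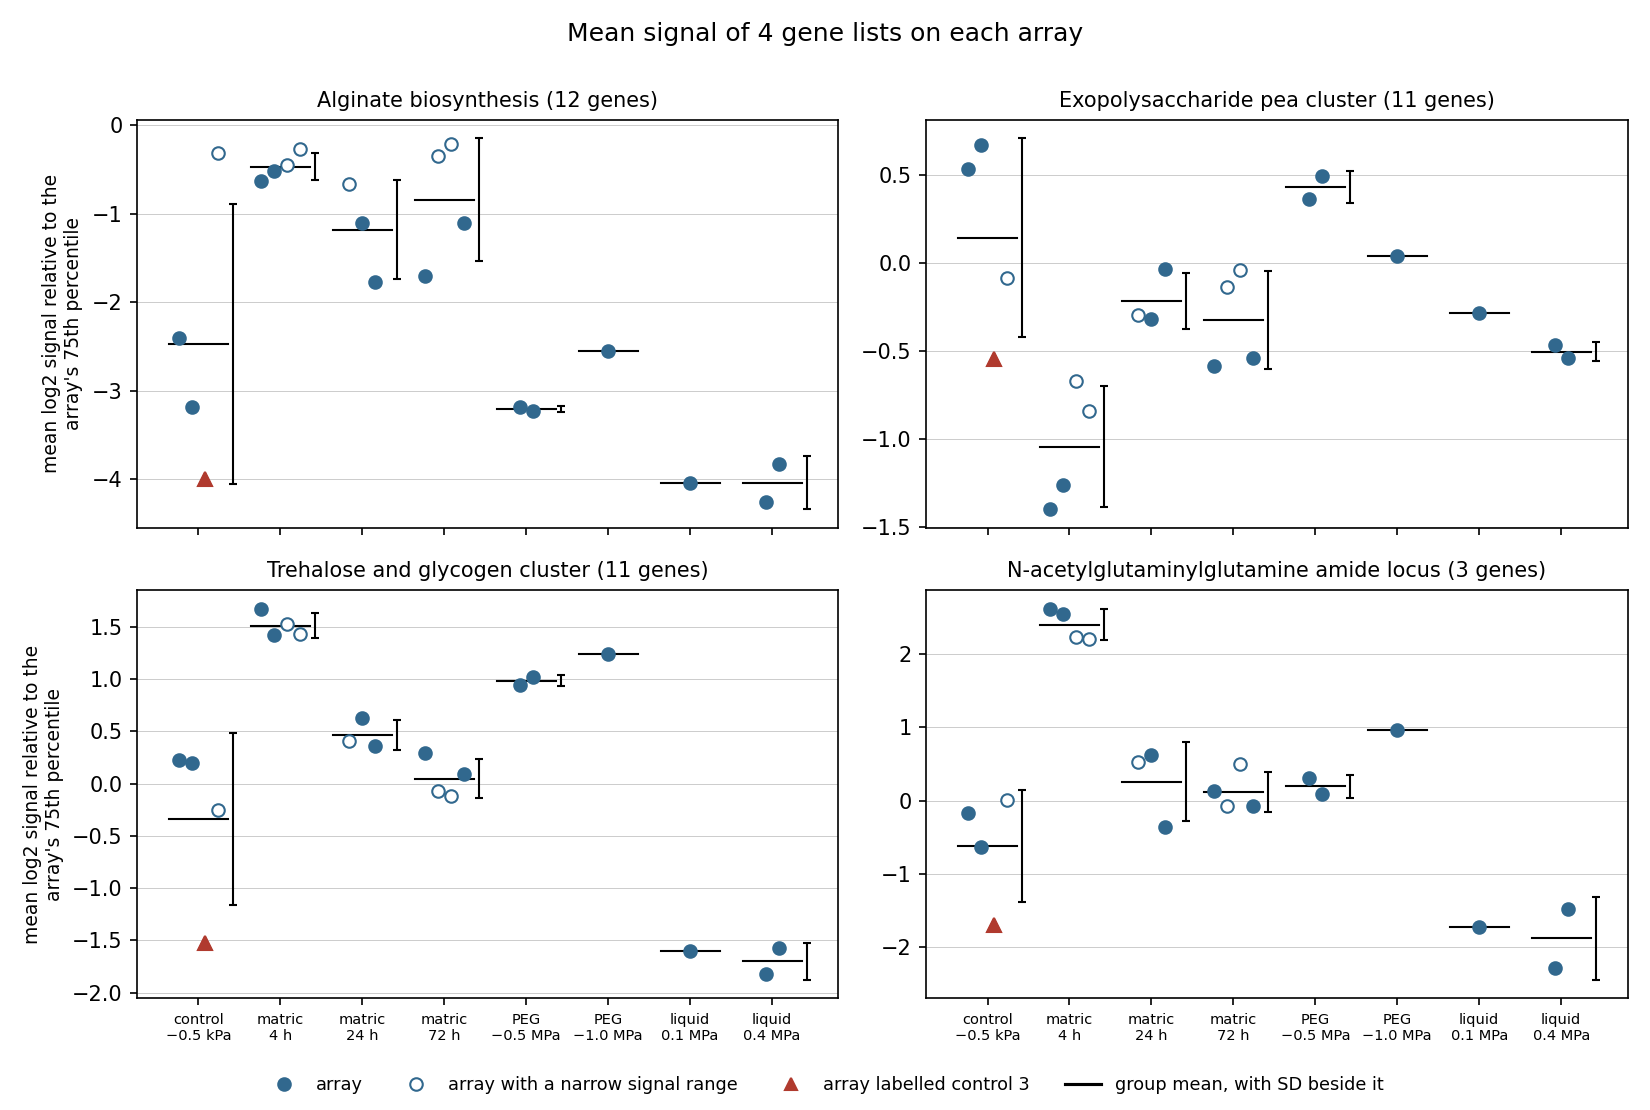
Mean log2 signal of the genes of 4 lists on each of the 21 arrays, relative to the 75th percentile of the array, with a line at each group mean and the SD beside it, open circles for the 6 narrow arrays and a triangle for control replicate 3. The alginate genes averaged -0.47 at 4 h and -2.48 in the 4 controls, whose values spread more widely than those of the 4 h arrays.

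At 24 h the alginate genes stood higher and the pea genes lower than in the controls as lists, while no single gene passed. The alginate list had a median of 1.17 (camera adjusted p = 1.03e-06, adjusted p = 0.275 with an estimated correlation), with 0 of 12 genes called by limma and 1 adjusted over the list alone. PP_1278 changed by 1.58 (SE 0.44, adjusted p = 0.179) and PP_1288 by 2.12 (SE 0.72, adjusted p = 0.333). The change of PP_1288 was 1.43 without control replicate 3 and 3.00 without control replicate 4. The pea list had a median of -0.34 (adjusted p = 0.00184, adjusted p = 0.350 with an estimated correlation), and its call was lost without 24 h replicate 1 (adjusted p = 0.152) or control replicate 2 (0.120). Its shift relative to all genes, -0.40, was -0.066 and -0.11 in those fits, -0.70 without 24 h replicate 3, -0.21 without control replicate 1 and -0.90 without control replicate 4. The flagellum list had a median of 0.45 (adjusted p = 2.85e-05, adjusted p = 0.350 with an estimated correlation), and its call was lost within slide 2 (adjusted p = 0.116) and without control replicate 4 (0.0881). Its shift of 0.39 was 0.70, 0.83 and -0.31 without 24 h replicates 1, 2 and 3, and 0.62 and 0.064 without control replicates 3 and 4. The polyhydroxyalkanoate cluster had a median of -0.37 (adjusted p = 0.0232, adjusted p = 0.248 with an estimated correlation), and lost its call with quantile normalization (0.0555) and without 24 h replicate 1 (0.152) or control replicate 1 (0.0828), 2 (0.103) or 3 (0.192). Its shift of -0.43 was -0.13 without 24 h replicate 1 and -0.29, -0.27 and -0.93 without control replicates 2, 3 and 4. Medians of the trehalose and glycogen list (0.69, adjusted p = 4.9e-05) and the NAGGN list (0.98, adjusted p = 0.0232) both had adjusted p = 0.248 with an estimated correlation, and both calls were lost without control replicates 3 and 4, with adjusted p = 0.827 and 0.321, with slide as a block (0.571 and 0.522), within slide 2 (0.934 and 0.132) and without control replicate 3 and the narrow arrays (0.127 and 0.334). The NAGGN call was also lost without 24 h replicate 2 (adjusted p = 0.155) or control replicate 3 (0.131) or 4 (0.0827), with shifts of 0.59 in the first of these fits and also in the fit without control replicate 3, against 0.91 with all arrays. The trehalose and glycogen shift went from 0.62 to 1.06 without 24 h replicate 1.

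At 24 h limma called 0 of 5349 genes against the controls, with 418 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0663. The omission of control replicates 3 and 4 gave 122 genes higher and 53 lower, among them 5 alginate genes higher and 4 pea genes lower, and the omission of control replicate 4 alone gave 109 genes. Without control replicate 3 alone 1 gene was called. With both left out PP_1278 rose by 1.61 (adjusted p = 0.0116), PP_1288 by 2.40 (adjusted p = 0.00801), PP_3494 by 4.45 (adjusted p = 0.00959) and PP_3505 by 3.10 (adjusted p = 0.00233), and PP_3698 and PP_3697 changed by -3.17 and -2.76 (both adjusted p = 0.00141). The omission of control replicate 4 alone was enough for calls of PP_1278 (adjusted p = 0.0115), PP_1288 (0.0067), PP_3494 (0.00548) and PP_3505 (0.00111). With all arrays PP_3698 and PP_3697 both changed by -0.89 and were not called. They changed by -0.13 and -0.24 without control replicate 2, and by -2.21 and -1.98 without control replicate 3. Of the 10 fixed lists 8 passed camera, 0 with an estimated correlation and 0 with fry, and camera passed 4 without control replicate 4 and 5 without 24 h replicate 1, control replicate 2 or control replicate 3. Of the 14 added lists 7 passed camera at 24 h, 2 higher and 5 lower, and 0 passed with an estimated correlation. Without control replicate 3 and the narrow arrays 0 of the 14 passed camera. With slide as a block 1 gene was called. Within slide 2, with 3 stress arrays and 1 control array, 0 genes were called by limma, and the list shifts were 1.63 for alginate and -1.29 for pea. Quantile normalization gave 75 genes.

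At 72 h the alginate genes again stood higher and the pea genes lower as lists. The alginate list had a median of 1.51 (camera adjusted p = 2.35e-11, adjusted p = 0.138 with an estimated correlation), with 0 of 12 genes called by limma and 7 adjusted over the list alone. PP_1278 changed by 1.61 (SE 0.40, adjusted p = 0.217) and PP_1288 by 2.58 (SE 0.67, adjusted p = 0.226). The change of PP_1288 was 1.89 without control replicate 3 and 3.46 without control replicate 4. The pea list had a median of -0.37 (adjusted p = 1.16e-08, adjusted p = 0.138 with an estimated correlation), with 2 of 11 genes called when adjusted over the list alone. Its shift relative to all genes, -0.60, was -0.31 without control replicate 2 and -0.95 without control replicate 4. The medians were 1.89 for alginate and -1.03 for pea without control replicates 3 and 4. Of the 14 added lists 9 passed camera, 1 higher and 8 lower, and 0 passed with an estimated correlation. Without control replicate 3 and the narrow arrays 0 of the 14 passed camera. The ribosomal protein genes among them, which follow growth in many bacteria, had a median of -0.62 (camera adjusted p = 6.58e-10, adjusted p = 0.347 with an estimated correlation). The shift of that list relative to all genes was -0.85. The call was lost with quantile normalization at a shift of -0.24, without control replicate 3 at -0.14 and without control replicate 3 and the narrow arrays at -0.18. It stayed without 72 h replicate 3 at a shift of -0.32, without control replicate 4 at -1.88, without control replicates 3 and 4 and with slide as a block at -1.47 each, within slide 1 at -0.88 and within slide 2 at -2.16. The polyhydroxyalkanoate cluster had a median of -0.31 (adjusted p = 0.0380, adjusted p = 0.138 with an estimated correlation), and lost its call with quantile normalization (0.225), within slide 2 (0.0523), without control replicate 3 and the narrow arrays (0.254), and without 72 h replicate 2 (0.105) or 3 (0.115) or control replicate 1 (0.0978), 2 (0.0804) or 3 (0.362). Its shift of -0.54 was -0.26 and -0.31 without 72 h replicates 2 and 3 and -0.32 without control replicate 3. The NAGGN list (median 0.60, adjusted p = 0.107) and the trehalose and glycogen list (median 0.33, adjusted p = 0.234) were not called.

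At 72 h limma called 1 gene against the controls, with 326 at an unadjusted p under 0.05. PP_3494 rose 16.6-fold (log2 4.05, SE 0.61, adjusted p = 0.0341), from -1.60 ± 0.95 (SD, n = 4) to 2.45 ± 1.30 (SD, n = 4). The median of all genes was 0.23 with all arrays and 0.44 without control replicates 3 and 4. That omission gave 137 genes higher and 77 lower, among them 6 alginate genes higher and 5 pea genes lower. In that fit PP_1278 rose by 1.63 (adjusted p = 0.00829), PP_1288 by 2.86 (adjusted p = 0.00163) and PP_5338 by 3.12 (adjusted p = 0.000796), and PP_3698 and PP_3697 changed by -3.11 and -2.83. With all arrays PP_5338, PP_3698 and PP_3697 changed by 1.62, -0.84 and -0.96 and were not called. PP_3698 and PP_3697 changed by -0.075 and -0.31 without control replicate 2, and by -2.15 and -2.05 without control replicate 3. Without control replicate 4 alone the calls included PP_1278 (adjusted p = 0.00611), PP_1288 (0.00142) and PP_5338 (0.0490). The count was 118 without control replicate 4, 23 without 72 h replicate 3, and 0 by limma without 72 h replicate 1 or 4 or without control replicate 1, 2 or 3, where PP_3494 had an adjusted p of 0.105 to 0.211. Of the 10 fixed lists 5 passed camera, 0 with an estimated correlation and 0 with fry, and 3 passed camera without control replicate 3. A slide block gave 31 genes higher and 15 lower. Within slide 1 and within slide 2 (2 stress arrays and 1 control array each) 0 genes were called by limma, and the list shifts were 1.01 and 1.95 for alginate and -1.37 and -1.53 for pea.

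**Figure D3:**
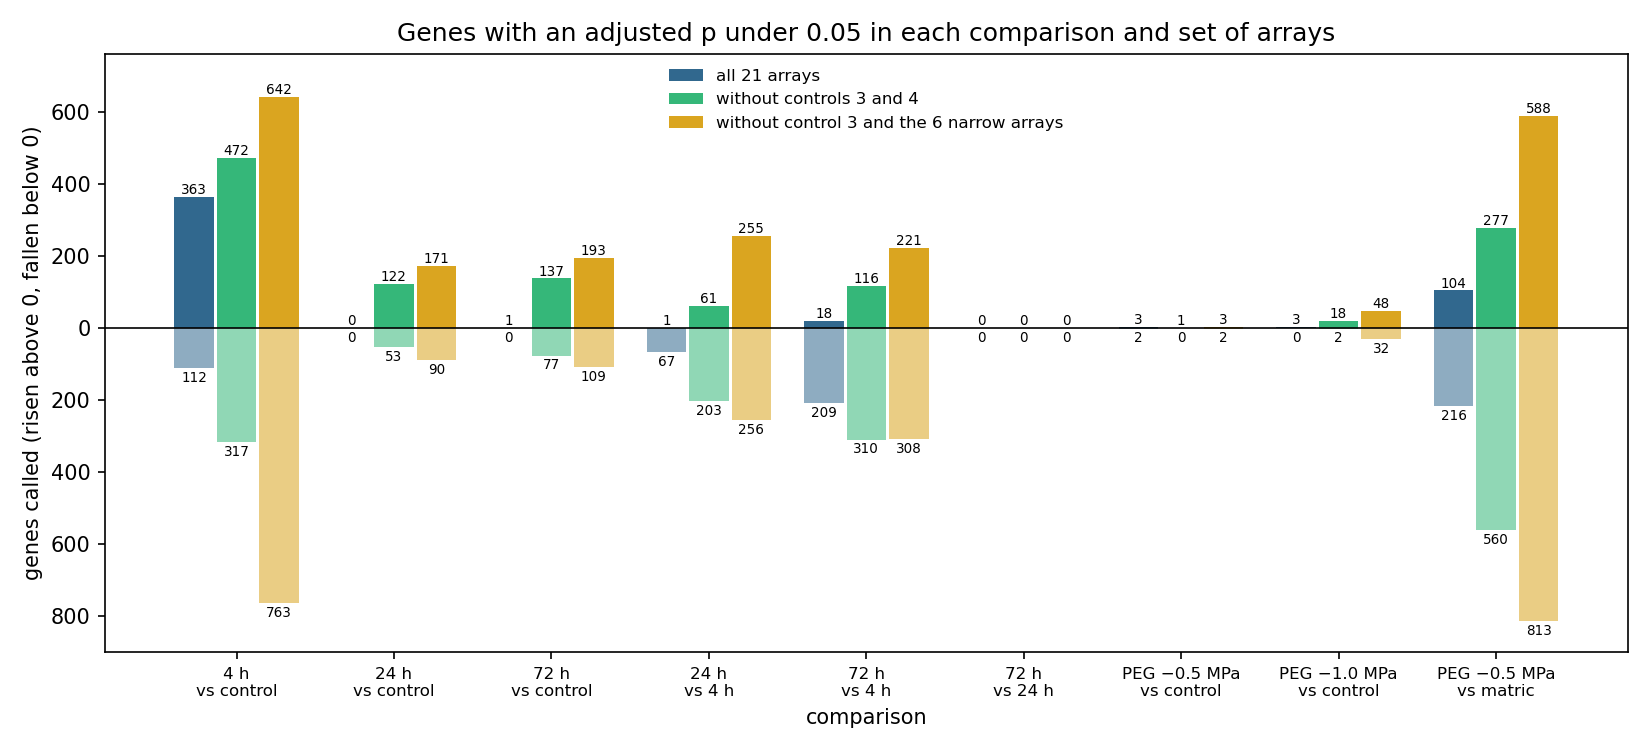
Number of genes called higher and lower in each comparison with all arrays, without control replicates 3 and 4, and without control replicate 3 and the narrow arrays. The 4 h comparison gave 363 higher and 112 lower with all arrays, and 472 and 317 without control replicates 3 and 4.

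The overlap of the 3 time points answered which genes moved the same way throughout. With all arrays 0 genes were called at all 3 times by limma, since 0 were called at 24 h. Without control replicates 3 and 4, 75 genes were higher and 44 lower at all 3 times. In that fit 114 higher and 49 lower genes were shared between 4 h and 24 h, where independent lists of these sizes would share 10.8 and 3.14. The groups shared their control arrays, so the lists were not independent. The excess over these values therefore does not by itself show a shared response. When 4 h was compared with control replicates 1 and 2 and 24 h with control replicates 3 and 4, 20 genes were shared, and 61 with the controls exchanged. Control replicates 3 and 4, an array resembling the liquid cultures and a narrow one, formed 1 side of each division. With 72 h compared with control replicates 3 and 4, limma called 0 genes at 72 h (443 at an unadjusted p under 0.05), so it shared 0 with 4 h and with 24 h. With 72 h compared with control replicates 1 and 2 and the earlier time with control replicates 3 and 4, it shared 32 genes with 4 h and 0 with 24 h. All 3 times shared 52 genes without control replicate 4 and 1 gene without 72 h replicate 2.

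From 4 h to 72 h the NAGGN, trehalose and glycogen, and envelope stress genes fell, while the betaine locus was not called (median 0.32, adjusted p = 0.794). In the trehalose and glycogen list 7 of 11 genes fell, 10 when adjusted over the list alone, with a median of -1.62 (camera adjusted p = 3.85e-13, adjusted p = 0.0239 with an estimated correlation). The NAGGN list had a median of -1.93 with 2 of 3 genes called (adjusted p = 3.10e-07, adjusted p = 0.00919 with an estimated correlation), and PP_1750 fell by 3.08 (SE 0.37, adjusted p = 0.000208). The algU-muc list had a median of -2.28 with 3 of 4 genes called (adjusted p = 0.000225, adjusted p = 0.0182 with an estimated correlation), and its shift relative to all genes went from -2.60 to -2.01 without 72 h replicate 3. The alginate list had a median of -0.28 (adjusted p = 0.0342, adjusted p = 0.760 with an estimated correlation), a call lost with slide as a block (0.0502) and without 4 h replicate 1 (0.0505) or 2 (0.0540) or 72 h replicate 1 (0.141). The pea list had a median of 0.75 (adjusted p = 0.000123, adjusted p = 0.348 with an estimated correlation) and the list for breakdown of aromatic acids -0.54 (adjusted p = 0.000225, adjusted p = 0.622 with an estimated correlation, and 0.129 with quantile normalization). The shift of the aromatic acid list, -0.86, was -0.57 without 4 h replicate 1, -0.53 without 72 h replicate 2 and -0.35 without 72 h replicate 3. PP_3975 rose 5.30-fold (log2 2.40, SE 0.41, adjusted p = 0.0023) and PP_3976 rose 4.97-fold, while PP_3265 fell by 3.44 (SE 0.83, adjusted p = 0.0245) and PP_1744 changed by -3.41 (SE 0.73, adjusted p = 0.0114). The calls of PP_3265 and of PP_4060 (-1.89, adjusted p = 0.0399) stayed without 72 h replicate 1 and were lost without any one of the other 7 arrays (adjusted p = 0.0507 to 0.0855 and 0.0550 to 0.136).

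The test of 72 h against 4 h called 227 genes, 18 higher and 209 lower, with the median of all genes at 0.32. Without control replicates 3 and 4, which enter this contrast only through the shared spread, 116 were higher and 310 lower. Without control replicate 3 and the narrow arrays 221 were higher and 308 lower. The count was 128 without 4 h replicate 1 and 143 without 72 h replicate 2. A slide block gave 165 genes, and within slide 1 (2 arrays against 4) limma called 0 of them with 490 at an unadjusted p under 0.05. Within slide 1 the list shifts were -1.73 for trehalose and glycogen, -2.38 for NAGGN and -2.27 for algU-muc.

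From 4 h to 24 h the same lists fell. The trehalose and glycogen list had a median of -1.15, with 0 of 11 genes called by limma over all genes and 7 adjusted over the list alone (camera adjusted p = 7.51e-09, adjusted p = 0.0893 with an estimated correlation). The NAGGN list had a median of -2.05 with 2 of 3 genes called (adjusted p = 7.75e-08, adjusted p = 0.00639 with an estimated correlation), and PP_1750 fell by 2.38 (SE 0.40, adjusted p = 0.00716). The algU-muc list had a median of -1.42 (adjusted p = 0.0175, adjusted p = 0.117 with an estimated correlation, and 0.0612 without 24 h replicate 1) and the pea list 0.85 (adjusted p = 7.51e-09, adjusted p = 0.113 with an estimated correlation). The comparison called 1 gene higher and 67 lower, with the median of all genes at 0.14, 61 higher and 203 lower without control replicates 3 and 4, and 255 higher and 256 lower without control replicate 3 and the narrow arrays, so the balance of directions depended on those arrays. The count was 23 without 4 h replicate 1, 33 without 4 h replicate 2, and 31, 30 and 38 without 24 h replicates 1, 2 and 3. All 4 h arrays lay on slide 1 and all 24 h arrays on slide 2. With slide as a block, which then rests on the 72 h and control arrays, 0 genes were called by limma, with 205 at an unadjusted p under 0.05. All 68 genes called without the block kept their direction and had an unadjusted p under 0.05, and their median change went from -1.68 (median SE 0.31) to -1.58 (median SE 0.42), so the calls ended with the larger error and little change in fold. The algU-muc list lost its call (adjusted p = 0.0737) with its shift relative to all genes going from -1.56 to -1.20. The trehalose and glycogen, NAGGN and pea lists kept theirs, with shifts from -1.29 to -1.18, from -2.19 to -2.41 and from 0.71 to 0.59. Between 72 h and 24 h limma called 0 genes, with 43 at an unadjusted p under 0.05, and 0 without control replicates 3 and 4 with 139 at an unadjusted p under 0.05.

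With PEG at -0.5 MPa the trehalose and glycogen list was higher than in the controls, as it was at 4 h of matric stress. Its median was 1.64 (camera adjusted p = 9.04e-14, adjusted p = 0.0407 with an estimated correlation), with 0 of 11 genes called by limma over all genes and 9 adjusted over the list alone. The median was 0.74 without control replicates 3 and 4 (adjusted p = 0.0119 with an estimated correlation), and within slide 3, where the controls were replicates 3 and 4, its shift was 2.85. The NAGGN list had a median of 0.76 (adjusted p = 0.0083, adjusted p = 0.198 with an estimated correlation), a call lost with slide as a block (0.0652) and without control replicate 3 and the narrow arrays (0.0571), and its shift relative to all genes went from 1.06 to 0.69 without control replicate 3. Chaperone and heat shock protease genes, which handle misfolded proteins, had a median of 0.60 (adjusted p = 0.000168, adjusted p = 0.380 with an estimated correlation), and a shift that went from 0.90 to 0.35 without control replicate 4. The flagellum list had a median of 0.18 (adjusted p = 0.000885, adjusted p = 0.567 with an estimated correlation, 0.0532 without control replicate 4, where the shift went from 0.48 to 0.20, and 0.0949 with slide as a block). Of the 10 fixed lists 7 passed camera, 1 with an estimated correlation and 1 with fry, and 3 passed camera without control replicate 4. The alginate list had a median of -0.75 (adjusted p = 0.0805) and was not called. The type VI secretion list had a median of -0.57, while camera gave it as higher (adjusted p = 0.0083, adjusted p = 0.716 with an estimated correlation) with 2 of 56 genes called higher.

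With PEG at -0.5 MPa limma called 3 genes higher and 2 lower, with 427 at an unadjusted p under 0.05 and the median of all genes at -0.30. PP_4605 rose 21.2-fold (log2 4.41, SE 0.42, adjusted p = 9.6e-05), from -2.30 ± 0.72 (SD, n = 4) to 2.10 ± 0.07 (SD, n = 2). PP_3108, of the type VI secretion loci, rose 4.28-fold (log2 2.10, SE 0.38, adjusted p = 0.0486). PP_4244 fell by 2.16 (SE 0.36, adjusted p = 0.0350) and PP_4217 fell by 2.06 (SE 0.37, adjusted p = 0.0486). Only PP_4605 was called without control replicates 3 and 4, with adjusted p = 7.54e-05. The count was 1 without PEG replicate 1 or control replicate 2, 3 without control replicate 1 and 2 without control replicate 4. PP_3108 lost its call without any one of the 6 arrays (adjusted p = 0.0596 to 0.943). PP_4244 lost it without PEG replicate 1 (0.975) or control replicate 2 (0.0750) or 4 (0.0676), and PP_4217 without any array but control replicate 3 (0.0791 to 0.975). With slide as a block this contrast rests on control replicates 3 and 4, the only controls on slide 3, as does that of PEG at -1.0 MPa. That fit gave 246 genes, and within slide 3 limma called 0. The series table, whose columns for control replicates 3 and 4 matched the files of replicates 1 and 2, gave far more calls for both PEG levels.

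With PEG at -1.0 MPa, a single array, the trehalose and glycogen list had a median 2.83-fold higher than in the controls (camera adjusted p = 3.61e-13, adjusted p = 0.0360 with an estimated correlation), with 4 genes called adjusted over the list alone. The NAGGN list had a median of 1.28 (adjusted p = 0.000336, adjusted p = 0.0360 with an estimated correlation). Without control replicates 3 and 4 the medians were 0.78 and 1.03, with adjusted p = 0.0211 and 0.0739 with an estimated correlation, and the shift of the trehalose and glycogen list relative to all genes went from 1.86 to 0.97. PP_4605 rose 11.5-fold (log2 3.52, SE 0.54, adjusted p = 0.0412) and PP_2723 rose 7.85-fold (log2 2.97, SE 0.51, adjusted p = 0.0486), 2 of 3 genes called, all higher. The omission of control replicates 3 and 4 left 18 genes higher and 2 lower, with adjusted p = 0.00759 for PP_4605 and 0.00858 for PP_2723. The count was 0 by limma without control replicate 1 or 2, with 366 genes at an unadjusted p under 0.05 in the full comparison, and 21 without control replicate 3. PP_4605 and PP_2723 both had adjusted p = 0.0582 without control replicate 1 and 0.0956 without control replicate 2. Of the 10 fixed lists 3 passed camera, 2 with an estimated correlation and 2 with fry, and 5 passed camera without control replicate 3. Slide as a block gave 75 genes, and within slide 3 limma called 0. Between PEG at -1.0 and -0.5 MPa limma called 0 genes, with 19 at an unadjusted p under 0.05, and 0 without control replicates 3 and 4 with 73 at an unadjusted p under 0.05.

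Against the mean of the 3 matric groups, PEG at -0.5 MPa gave lower alginate and higher pea levels. Narrow arrays lay in the matric groups and not among the PEG arrays, so array type and treatment were partly confounded here. The median of all genes was -0.44 with all arrays and -0.036 without control replicate 3 and the narrow arrays. The values that follow are with all arrays unless stated. The alginate list had a median of -2.23 with 6 of 12 genes called lower, 11 adjusted over the list alone (camera adjusted p = 3.05e-07, adjusted p = 0.348 with an estimated correlation). The pea list had a median of 1.04 with 3 of 11 genes called higher (adjusted p = 2.61e-09, adjusted p = 0.140 with an estimated correlation). The chaperone list had a median of 1.04 with 3 of 12 genes called higher (adjusted p = 7.15e-06, adjusted p = 0.120 with an estimated correlation). The lap list had a median of 1.03 with 3 of 5 genes called higher (adjusted p = 0.00953, adjusted p = 0.111 with an estimated correlation), a call lost with slide as a block (0.212) and with quantile normalization (0.0766), and the polyhydroxyalkanoate list 0.80 with 1 of 6 (adjusted p = 0.00313, adjusted p = 0.0710 with an estimated correlation). PP_2007 was 88.4-fold higher (log2 6.47, SE 1.32, adjusted p = 0.0132) and PP_1660 54.9-fold higher (log2 5.78, adjusted p = 0.00868), while PP_3494 changed by -4.80 (SE 0.66, adjusted p = 0.00122) and PP_5338 by -4.26 (SE 0.65, adjusted p = 0.0027). Without PEG replicate 1 none of these 4 genes was called (adjusted p = 0.0729 to 0.240), and without PEG replicate 2 only PP_3494 was. The change of PP_2007 was 5.86 without 24 h replicate 2.

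In all, 104 genes were higher and 216 lower with PEG at -0.5 MPa than under matric stress, with the median of all genes at -0.44. Quantile normalization gave 132 higher and 98 lower. Without control replicates 3 and 4, 277 were higher and 560 lower, and without control replicate 3 and the narrow arrays 588 were higher and 813 lower. The count was 1 without PEG replicate 1 and 29 without PEG replicate 2. All PEG arrays lay on slide 3 and all matric arrays on slides 1 and 2, so slide and treatment were joined only by the controls. Slide as a block gave 586 genes. Across genes, which are not independent replicates, the fold changes of PEG at -0.5 MPa and of the matric mean against the shared controls correlated at 0.103 (Pearson) and -0.105 (Spearman). Simulations without any effect, with noise independent between arrays, gave a Pearson value of 0.493 from the shared controls alone. They lacked deviations that real arrays share, so the gap to them does not show opposed responses. The covariance was 0.0432 against 0.169 in these simulations, and without control replicate 3 and the narrow arrays 0.0716 against 0.0718. With the controls divided between the comparisons the value was -0.527 or 0.0341, depending on which pair served the matric groups. It was 0.206 without 24 h replicate 1, 0.00857 without 24 h replicate 3, 0.296 without control replicate 1 and 0.352 without control replicate 2. For PEG at -1.0 MPa the covariance was 0.0966 against 0.169 in the simulations, and 0.137 against 0.0717 without control replicate 3 and the narrow arrays. The correlation was 0.200 against 0.381 in the simulations, and 0.290, 0.366 and 0.393 without 24 h replicate 1, control replicate 1 and control replicate 2.

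Gas pressure of 0.4 MPa in liquid culture tested pressure itself apart from water potential. Against the array at 0.1 MPa limma called 0 of 5349 genes, with 0 at an unadjusted p under 0.05 and, without control replicates 3 and 4, 0 called with 5 at an unadjusted p under 0.05. The ribosomal protein cluster had a median of 0.60 with 0 of 32 genes called by limma (camera adjusted p = 1.55e-13, adjusted p = 0.381 with an estimated correlation). The median SE of a log2 fold change was 0.81 with 2 arrays against 1.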

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

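The comparison of control replicate 3 with the liquid culture arrays, the tests of background and of matric stress for the narrow arrays, and the tests of slide, narrow arrays and duration for the number of calls at 4 h were chosen only after the result was seen.

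In 15 of 189 groups of 4 arrays, 1 array stood far from the others, where chance flags about 1 in 20 groups. Of the 15, 5 were control replicate 4 and 4 were control replicate 3. Control replicate 4 stood apart for PP_4395 (-0.052), PP_1427 (1.02), PP_1428 (1.17), the type VI secretion list (-0.21, the others -2.45 to -2.11) and the polyhydroxyalkanoate list (0.16). Control replicate 3 stood apart for PP_1378 (-2.79), PP_3265 (-6.33, the others -1.45 to -0.92), the NADH dehydrogenase list (0.73) and the terminal oxidases (1.78, the others 0.02 to 0.12). The remaining 6 were 72 h replicate 4 for PP_3134 (-0.64) and PP_2006 (2.55), 72 h replicate 1 for PP_1428 (4.08) and PP_2723 (0.69), 4 h replicate 1 for PP_4395 (4.51) and 4 h replicate 2 for PP_5338 (0.18).

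Differences between time points passed the test in 35 results for genes and lists named in the report. Of these 9 were from 4 h to 24 h and 26 from 4 h to 72 h, and the same 9 genes and lists recur among the 26. PP_3975, PP_3976, PP_3265 and PP_1744 were named as the largest called genes from 4 h to 72 h, so their passing there was given in advance. The other genes had been named for large changes at 4 h against the controls. That choice used the same 4 h arrays, which favours a change back in these contrasts. List values here are relative to the median of all genes. From 4 h to 24 h the NAGGN list changed by -2.19, the algU-muc list by -1.56, the trehalose and glycogen list by -1.29 and the pea list by 0.71. The genes were PP_1750 (-2.38), PP_1749 (-2.001), PP_1378 (-2.48), PP_1379 (-1.58) and PP_3852 (-1.46). From 4 h to 72 h the lists changed by -1.95 for trehalose and glycogen, -2.26 for NAGGN, -2.60 for algU-muc, -0.60 for alginate, -0.86 for breakdown of aromatic acids and 0.43 for pea. With an estimated correlation the NAGGN list passed from 4 h to 24 h and the trehalose and glycogen (adjusted p = 0.0893), algU-muc (0.117) and pea (0.113) lists did not. From 4 h to 72 h the trehalose and glycogen, NAGGN and algU-muc lists passed it, and alginate (0.760), aromatic acids (0.622) and pea (0.348) did not. In the trehalose and glycogen cluster PP_4060 (-1.89), PP_4050 (-2.33) and PP_4051 (-2.05) fell, as did PP_1750 (-3.08) and PP_1749 (-1.83) of the NAGGN locus. So did PP_4395 (-2.23), PP_4396 (-2.41), PP_1427 (-2.44), PP_1428 (-2.35), PP_1429 (-2.21), PP_1378 (-3.16), PP_1379 (-1.77), PP_1380 (-1.36), PP_3852 (-1.27), PP_3265 (-3.44), PP_1502 (-3.04) and PP_1744 (-3.41). PP_4364 (1.45), PP_3975 (2.40) and PP_3976 (2.31) rose.

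The scanner file of control replicate 3 resembled the liquid culture arrays. Across genes, its difference from control replicate 1 followed the difference of the liquid arrays from control replicate 2 with a slope of 0.955, where the highest matric array gave 0.202. The lowest liquid culture array gave 0.945, but these arrays form the mean they are set against, so a high slope was given in advance. An effect of slide 3 was excluded, since the PEG arrays on that slide gave slopes of 0.0179 to 0.0342. A liquid culture sample under the label of this control is consistent with the slope, and it stays a hypothesis, since the resemblance was seen before the test. The design gave no biological explanation to test.

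The range of signal was narrow on 6 arrays. Negative control spots on these arrays had 0.952 times the median of the other arrays. Their signal was already corrected for background, so a similar level was partly given in advance. The mean local background before correction was 17.7 to 34.0 on the narrow arrays and 16.3 to 49.4 on the others. The 1st percentile of the gene spots was 15.8 times as high, so these values argue against local or scanner background as the cause. Matric stress by itself did not make an array narrow, since 4 of 4 control and matric groups and all 3 slides held both kinds of array. A part of matric stress was not excluded, since control replicate 4 was the only narrow control. Its file correlated with those of 72 h replicates 3 and 2 at 0.911 and 0.834. A signal added to the gene probes, which differs from probe to probe and is shared between arrays, may explain the pattern: the deviations of narrow arrays from their groups correlated at 0.735 on average over 13 pairs of different groups (0.591 to 0.890), against a mean absolute value of 0.193 over 12 pairs of other matric arrays. What would add such a signal, for example carried-over DNA, was not tested.

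More genes were called at 4 h than at 24 h or 72 h with all arrays. Array weights, whose fit stopped before convergence, turned the order round, with 3096 genes at 72 h against 1730 at 4 h. The narrow arrays and control replicate 3 were excluded as the whole cause, since without them the count at 4 h was 4.65 times the higher of the other counts. Slide was excluded as the whole cause in the same way, with a ratio of 8.02 with slide as a block. The duration of the stress, the biological difference between these groups, stays open. Its test within slide 1 called 0 genes by limma between 72 h (2 arrays) and 4 h (4 arrays) with 490 at an unadjusted p under 0.05. Of the 10 fixed lists 5 passed camera there, and 0 with an estimated correlation (smallest adjusted p of 0.0526), so the test does not decide.

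Chance was tested with 35 splits of the arrays for each comparison of groups with at least 3 arrays. At 4 h (475 genes called) the highest other split gave 0, so 1 of the 35 gave as many. The same held from 4 h to 24 h (68 called, highest other 0, 1 of the 35). That is the smallest share that 35 splits can give, so it counts against chance without excluding it over several comparisons. Every other split mixes arrays of both groups, which can widen the spread and lower the calls whatever caused the difference. All 4 h arrays lay on slide 1, where control replicate 1 was the only control. The split of 4 h against 24 h is also that of slide 1 against slide 2, and with slide as a block 0 genes were called by limma, with 205 at an unadjusted p under 0.05. All 68 kept their direction in that fit, and their median change went from -1.68 (median SE 0.31) to -1.58 (median SE 0.42), so the calls ended with the larger error, and the folds count against slide as the whole cause. Chance cannot be excluded for the genes called at 72 h (1, highest other 2649, 6 of 35) or from 4 h to 72 h (227, highest other 2366, 2 of 35). At 24 h and from 24 h to 72 h limma called 0 genes (418 and 43 at an unadjusted p under 0.05), so every split gives as many and the test says nothing (highest other 148 and 2686). The split with 2366 genes puts the 4 arrays with a wide range of signal against the 4 narrow ones, that with 2686 does the same for 4 against 3 arrays, and that with 2649 puts 4 wide arrays against 3 narrow arrays and control replicate 1, so these counts point to the structure of the arrays and not to time. With slide as a block 165 genes were called from 4 h to 72 h. For the fixed lists chance cannot be excluded in any of the 6 comparisons: at 4 h 8 passed camera with 9 as the highest other (7 splits gave as many), at 24 h 8 with 8 (2 splits), at 72 h 5 with 8 (18 splits), from 4 h to 24 h 5 with 7 (20 splits), from 4 h to 72 h 5 with 8 (22 splits) and from 24 h to 72 h 4 with 6 (17 splits).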

How the results depend on the processing

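The fits without control replicates 3 and 4, without control replicate 3 and the 6 narrow arrays, within 1 slide, from the series table and with normexp were chosen only after the data had been seen. Results were counted once per named gene or list, comparison and alternative. The call of a gene stayed as it was in 1126, was gained in 55 and was lost in 114. The call of a list stayed as it was in 692 and was lost in 138, and the list reversed in 14. A change of direction was not counted for genes or lists called in neither fit. No filter and the median of the probes could not differ from the main values, and each gave 62 of the unchanged gene results. The cause was not tested for any change below, except that omissions leave fewer arrays. On each array 98.4 to 100% of the gene spots lay well above background.

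Lists that reversed did so at 4 h unless stated, with shifts relative to all genes. With slide as a block these were 0.13 for type VI secretion, 0.054 for the terminal oxidases and -0.35 for breakdown of aromatic acids. Without control replicates 3 and 4 they were 0.075 for type VI secretion and -0.37 for aromatic acids, and the omission of 1 array gave -0.34 to 0.095 for type VI secretion (highest without control replicate 4). The terminal oxidases gave -1.01 to 0.28 with 1 array left out (highest without control replicate 3), 0.34 without it and the narrow arrays, and 0.047 within slide 1, where aromatic acids gave -0.27. The series table gave 0.065 for type VI secretion, 0.012 for the terminal oxidases and -0.30 for aromatic acids. The flagellum list at 24 h gave -0.31 without 24 h replicate 3, the lowest of a range up to 0.83.

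Among the numbers of called genes, array weights, whose fit stopped before convergence, gave 1730 at 4 h, 1233 at 24 h, 3096 at 72 h, 817 for 24 h against 4 h, 408 for 72 h against 4 h, 482 for 72 h against 24 h, 877 for PEG at -0.5 MPa, 367 for PEG at -1.0 MPa, 4 between the PEG doses and 3688 for PEG against matric stress. A fit of only the groups compared gave 242 at 4 h, 0 at 72 h, 106 for 24 h against 4 h, 0 for PEG at -0.5 MPa, 0 for PEG at -1.0 MPa and 581 for PEG against matric stress. Quantile normalization gave 75 at 24 h, 33 at 72 h, 3 for PEG at -0.5 MPa and 0 for PEG at -1.0 MPa, with 16 genes called the same way at all 3 times and correlations of PEG with matric fold changes of 0.222 and 0.312. An intensity trend with robust spread gave 41 at 24 h, 22 at 72 h, 114 for 24 h against 4 h and 10 for PEG at -1.0 MPa. Normexp gave 40 at 24 h, 7 at 72 h, 2 for PEG at -0.5 MPa, 210 for PEG against matric stress and 6 genes at all 3 times. With 72 h replicate 1 counted as 24 h the counts were 46 at 24 h, 0 at 72 h and 126 for 24 h against 4 h.

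Slide as a block gave 1 at 24 h, 46 at 72 h, 0 for 24 h against 4 h, 246 for PEG at -0.5 MPa, 75 for PEG at -1.0 MPa and 586 for PEG against matric stress, with 5 lists at 24 h and 2 for PEG at -0.5 MPa. Within slide 1 there were 80 at 4 h, 0 at 72 h and 0 for 72 h against 4 h. Within slide 2 there were 0 at 72 h, with 4 lists at 24 h and 3 at 72 h. Within slide 3 there were 0 for PEG at -0.5 MPa and 0 at -1.0 MPa, with 5 lists at -1.0 MPa. The replicate number as a block gave 0 at 72 h, 43 for 24 h against 4 h, 2 for PEG at -0.5 MPa and 0 for PEG at -1.0 MPa. It gave 78 for PEG against matric stress and 396 at 4 h. Deviations from the group means correlated at -0.849 to 0.860 between arrays of the same number, which leaves pairing undecided.

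Without control replicates 3 and 4 there were 789 at 4 h, 175 at 24 h, 214 at 72 h, 264 for 24 h against 4 h, 426 for 72 h against 4 h, 1 for PEG at -0.5 MPa, 20 for PEG at -1.0 MPa, 837 for PEG against matric stress, 119 at all 3 times and 5 lists at 24 h. Without control replicate 3 and the narrow arrays there were 1405 at 4 h, 261 at 24 h, 302 at 72 h, 511 for 24 h against 4 h, 529 for 72 h against 4 h, 80 for PEG at -1.0 MPa, 2 between the PEG doses, 1401 for PEG against matric stress and 161 at all 3 times, with 5 lists at 24 h, 3 at 72 h and 7 for PEG at -1.0 MPa. The series table gave 830 at 4 h, 112 at 24 h, 141 at 72 h, 267 for 24 h against 4 h, 457 for 72 h against 4 h, 327 for PEG at -0.5 MPa, 387 for PEG at -1.0 MPa and 73 at all 3 times, with 5 lists at 24 h, 2 at 72 h and 6 for PEG at -1.0 MPa. Its PEG counts were against its columns for control replicates 3 and 4, which matched the scanner files of replicates 1 and 2. With split controls, 4 h against control replicates 3 and 4 gave 28 genes at all 3 times. Matric stress against control replicates 1 and 2 gave correlations of -0.527 and -0.428, and against replicates 3 and 4 it gave 0.115 for PEG at -1.0 MPa.

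Lists passing with an estimated correlation were 1 at 4 h, 0 at 24 h, 0 at 72 h, 1 for 24 h against 4 h, 2 for 72 h against 4 h, 1 for PEG at -0.5 MPa and 0 for PEG against matric stress. With fry they were 5 at 4 h, 0 at 24 h, 0 at 72 h, 3 for 24 h against 4 h, 1 for PEG at -0.5 MPa and 3 for PEG against matric stress.

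Omission of 1 array at a time gave 340 to 645 genes at 4 h (lowest without 4 h replicate 1, highest without control replicate 4), 0 to 109 at 24 h and 0 to 118 at 72 h (both highest without control replicate 4), 23 to 51 for 24 h against 4 h and 128 to 209 for 72 h against 4 h (both lowest without 4 h replicate 1), and 0 to 0 for 72 h against 24 h. For PEG it gave 1 to 7 at -0.5 MPa (lowest without replicate 1), 0 to 21 at -1.0 MPa (highest without control replicate 3), 0 to 0 between the doses and 1 to 343 against matric stress (lowest without PEG replicate 1), and 0 to 0 for gas pressure. Lists passing were 5 to 9 at 4 h, 4 to 7 at 24 h, 3 to 6 at 72 h, 4 to 6 for 24 h against 4 h, 4 to 7 for 72 h against 4 h, 3 to 9 for PEG at -0.5 MPa, 2 to 5 at -1.0 MPa and 5 to 6 for PEG against matric stress. Genes at all 3 times numbered 0 to 52, and the correlations ran from 0.00857 (without 24 h replicate 3) to 0.352 (without control replicate 2) at -0.5 MPa and from 0.122 (without 72 h replicate 1) to 0.393 (without control replicate 2) at -1.0 MPa. A group left with 1 array was assumed to vary like the others.

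Not run were normexp on the mean signal, since the files held no mean signal, and 1 fit of all columns of the series table, since its columns had been normalized as 2 sets.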

Other observations

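The tests of the liquid cultures against surface colonies were chosen only after the result was seen, and the test of neighbouring genes was planned before its result was known.

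Genes called at 4 h of matric stress lay beside each other on the chromosome, as genes of shared operons do. Of 5282 pairs of neighbouring locus tags, 170 were called the same way, against a mean of 26.6 and a highest value of 51 in 100000 permutations of the calls over the tags (permutation p = 1e-05, the smallest they can give). Of the 475 called genes 265 (55.8%) had such a neighbour, and 231 of the 265 were in no list. There were 29 runs of at least 3 risen genes and 6 runs of fallen genes. The longest risen run was PP_3255 to PP_3269, 15 genes with log2 fold changes of 2.28 to 4.95 and a median of 3.76. Fallen runs of 5 genes outside the lists were PP_0998 to PP_1002 at -3.02 to -2.06 with a median of -2.94 and PP_3126 to PP_3130 at -2.05 to -0.97 with a median of -1.38, and the run PP_3133 to PP_3138 of the pea cluster held 6 genes. The result is consistent with regulation of whole operons, and neighbours also share errors that follow the chromosome, which was not tested separately.

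Liquid cultures (3 arrays) differed from the surface colonies of control replicates 1 and 2 in 1124 genes by limma, 448 higher and 676 lower, with the median of all genes at -0.25. All liquid arrays lay on slide 3 and these controls on slides 1 and 2. Surface colonies with PEG also lay on slide 3, and across genes their differences from control replicate 1 followed the difference of the liquid arrays from control replicate 2 with slopes of 0.0179 to 0.0342, so slide 3 alone was excluded as the whole cause. Genes for breakdown of aromatic acids had a median of -3.38 with 16 of 17 called lower (camera adjusted p = 2.06e-15, adjusted p = 0.0133 with an estimated correlation). The terminal oxidases had a median of 2.22 with 9 of 13 called higher and 2 lower (adjusted p = 0.00319 with an estimated correlation). The trehalose and glycogen list had a median of -1.82 with 10 of 11 called lower (adjusted p = 0.0499 with an estimated correlation), and the peb exopolysaccharide cluster 2.62 with 7 of 8 called higher (adjusted p = 0.0517 with an estimated correlation). The alginate list had a median of -1.29 with 6 of 12 called lower (adjusted p = 0.491 with an estimated correlation).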
